A study of Mus musculus with 9 samples.

How the data were processed

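RNA of cultured macrophages was measured by sequencing in 9 libraries, 3 for each of bone marrow macrophages (BMM), fetal liver macrophages grown with L-cell supernatant (FLM_M) and fetal liver macrophages grown with GM-CSF (FLM_G). Per the labels' protocols, 250000 cells per well were plated in triplicate 1 day before harvest, genomic DNA was removed, and libraries were made with a TruSeq stranded mRNA kit and read for 101 cycles from 1 end on 1 lane of a HiSeq2500. Per the submitters' processing notes the tools were bcl2fastq, FastQC, cutadapt, HISAT2, StringTie and DESeq2 and the builds mm10 and GRCm38; which tool made which table is not given in the sources used here, nor are their versions. The authors deposited 2 tables over the same 46078 Ensembl genes, with a column per library. The first holds whole-number read counts per gene, deposited without normalization. The second holds FPKM (fragments per kilobase of transcript, relative to library size), as deposited by the authors.

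The counts were not taken as the main measure of the genes. They summed to 782400 to 1170813 per library, while the smallest steps of the FPKM put the libraries at 28390000 to 35470000 reads (the value of 1 read in genes with 1 annotated transcript; 18.0% to 21.4% of values below 5 reads lay within 2% of a read of a whole-read step, 3.6% by chance). With gene models of GENCODE M21 (GRCm38), in which 45143 of the 46078 identifiers were found, counts of genes with little FPKM followed the reads of the gene on the opposite strand, as detailed in the closing section. In 2381 protein-coding genes with an FPKM of at least 5 and no opposite-strand gene within 5 kb the counts did follow the gene's own FPKM (Spearman rho 0.831), at a median 0.63% of the reads implied by it. A stranded kit counted with the opposite setting would give such a table. The test named before the data were examined, edgeR on the counts, was therefore replaced by limma on the FPKM and kept as an alternative, a change made after the tables had been seen.

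FPKM were scaled between libraries by TMM factors (edgeR 4.0.16, unweighted, over genes passing the filter), carried over from the test first named before fold changes had been seen, and the factors ranged from 0.80 to 1.14. Genes with an FPKM of at least 1 in at least 3 libraries (11952) were tested on log2(FPKM + 1) with limma 3.58.1 (trend) in R 4.3.3, in a model with a mean per group over all 9 libraries and 6 residual degrees of freedom. Calls are at a Benjamini-Hochberg adjusted p under 0.05. Of 37 gene lists fixed before the data were examined, 30 had at least 5 tested members and entered camera with a preset inter-gene correlation of 0.01, adjusted over all lists and 3 comparisons together; the other 7 are given as levels. All list symbols were found, 3 under another name. Genes were named by a rule fixed beforehand, in which levels set for counts were read as scaled FPKM: per comparison the 8 largest increases and decreases among called genes whose groups did not overlap (3 against 3 do so by chance in 10% of genes), with a mean of at least 20 in the higher group and an assigned symbol; per described list up to 4 called members of the largest change, with a mean of at least 5, plus uncalled members with at least 50; and 20 macrophage, growth and sex genes fixed by name. Genes named in the closing section, the genes drawn in the figure of levels, and the markers of other cell types, Igf2bp3 and Hmga1 where not covered by the rule, were chosen after their values were seen. Some genes that the rule names are not reported here. FPKM values of 0 can be failed estimates: 6 genes were at 0 in 1 library of a group and at 5 FPKM or more in both others. In 20 genes reaching 20 FPKM, 1 library of a group lay over 4-fold from both others (29 cases). Some of these, such as Srxn1 and Egr1, were members of tested lists. Whether such values were failed estimates was not tested.

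Alternatives, planned for the counts and applied to the FPKM, were RLE and upper-quartile scaling, no scaling, no filter, a stricter filter (5 FPKM), a pseudocount of 0.1, only the 6 libraries compared, the replicate number as a block, a test against a 1.5-fold change, edgeR and DESeq2 1.42.0 on the counts, camera on log2 CPM of the counts, and each library left out. Quantile normalization, and the pseudocount of 0.1 on scaled values, were added after seeing the data. Simulated data held 200 changed genes, all above 5 FPKM in BMM, so recovery among lower genes was not measured. The limma step on FLM_M against BMM (11186 genes) recovered 89.6% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls. In FLM_G against BMM (11183 genes) it recovered 73.1%, 97% and 97%, with 11 false calls, and in FLM_G against FLM_M (11173 genes) 86.6%, 92.5% and 98.5%, with 10. Coordinates are those of GENCODE M21 by Ensembl identifier.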

Results

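The series compared macrophage cultures of C57BL/6J mice, an inbred laboratory strain. BMM were macrophages grown from bone marrow. FLM_M were macrophages grown from fetal liver of gestational day 15 to 19 in medium with 20% fetal bovine serum and 30% of the M-CSF-bearing supernatant of L cells (M-CSF, macrophage colony-stimulating factor). FLM_G were grown from fetal liver in medium with 30 ng/ml recombinant GM-CSF (granulocyte-macrophage colony-stimulating factor) and 10% fetal bovine serum. The medium of the BMM cultures is not described in the labels, and all cells had been in culture for at least 8 weeks. Each culture gave 3 libraries, 9 in total. The series title names M-CSF-responsive immortal macrophages as a model for macrophage function, and the question addressed by the comparisons is how the 3 cultures differ. Stranded poly(A) RNA libraries were sequenced for 101 cycles from 1 end. From the smallest steps in the FPKM values, the libraries held 28390000 (FLM_G replicate 1) to 35470000 reads (FLM_M replicate 3), so that 1 FPKM over 1 kb stood for about 28.4 to 35.5 reads. The deposited count table summed to only 782400 to 1170813 counts per library, and 36.1% of these lay in genes with a mean FPKM under 0.5 (closing section). All levels below are therefore FPKM, scaled between libraries, as mean ± SD over the 3 libraries of a group. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, with the standard error (SE) of the limma fit, and positions are whole genes on GRCm38. The libraries came from wells plated in triplicate and nothing says that they were separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical. Libraries of a group correlated across genes at Pearson 0.986 to 0.992, and libraries of different groups at 0.785 to 0.936.

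FLM_M cells differed from BMM most clearly in their antiviral and antigen-presentation genes, in chemokines, and in sterol and sugar metabolism. Of the 30 interferon-stimulated genes tested, 29 rose in FLM_M and 1 fell (camera, adjusted p = 3.52e-16; adjusted p = 0.0561 with an estimated correlation), with a median log2 fold change of 1.68. Cxcl10, a chemokine induced by interferon, rose from 3.72 ± 0.34 FPKM in BMM to 64.7 ± 10.0 in FLM_M. The antiviral gene Rsad2 rose from 2.51 ± 0.06 to 37.7 ± 5.6, and Ifit2 from 6.77 ± 0.37 to 85.6 ± 10.1. Zbp1, a nucleic acid sensor, was the member that fell, from 5.81 ± 0.35 to 0.76 ± 0.09. MHC class I presentation genes rose with them, 16 of 17 members against 1 that fell (camera, adjusted p = 3.92e-08; adjusted p = 0.0211 with an estimated correlation). H2-Q4 rose from 20.5 ± 0.9 to 65.0 ± 3.7 FPKM. H2-Q6 rose from 0.98 ± 0.04 to 30.7 ± 1.7, but reads of the H2-Q genes, which are near-identical copies, may have been divided between them. Calr, an endoplasmic reticulum chaperone, fell by 0.20 (SE 0.06) on the log2 scale with adjusted p = 0.0192, a call that 4 of the 9 fits without 1 library did not give and that was not made without scaling.

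Inflammatory cytokines and chemokines rose in FLM_M, 17 of 20 members against 2 that fell (camera, adjusted p = 2.09e-05; adjusted p = 0.0429 with an estimated correlation). Ccl12 (ENSMUSG00000035352, chromosome 11, 82101845 to 82103400) rose from 13.7 ± 1.0 to 221.2 ± 15.4 FPKM. Ccl4 rose from 33.5 ± 0.1 to 262.1 ± 16.2 and Ccl3 from 55.7 ± 2.2 to 324.6 ± 22.0. Among pattern recognition receptors 17 of 29 rose and 4 fell (camera, adjusted p = 0.000341; adjusted p = 0.135 with an estimated correlation). Cd14, the co-receptor for bacterial lipopolysaccharide, rose from 78.2 ± 1.2 to 201.9 ± 9.5 FPKM, and Marco, a scavenger receptor, from 5.27 ± 0.26 to 24.9 ± 1.5. Tlr2 rose from 23.3 ± 0.8 to 36.6 ± 1.8. Tlr4 stood at 2.25, 2.95 and 9.41 FPKM in the 3 BMM libraries and at 13.3, 11.1 and 2.88 in the FLM_M libraries, a wide spread within groups (log2 fold change 0.77, SE 0.56, limma adjusted p = 0.296; 1.37 and adjusted p = 0.0498 without FLM_M replicate 3). Fcgr2b, an inhibitory Fc receptor (ENSMUSG00000026656, chromosome 1, 170958617 to 170976547), rose from 4.91 ± 1.03 to 93.6 ± 7.5. The scavenger receptor Colec12 rose from 14.1 ± 0.8 to 222.8 ± 6.1, the complement component C3 from 3.93 ± 0.24 to 68.3 ± 4.8, and Cpe, a prohormone-processing carboxypeptidase, from 2.93 ± 0.17 to 53.7 ± 2.6. Fc, complement and scavenger receptors as a list did not pass (camera, adjusted p = 0.263, 11 of 23 higher and 8 lower).

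Genes of cholesterol synthesis were lower in FLM_M than in BMM, with 19 of 24 falling and none rising (camera, adjusted p = 7.65e-09; adjusted p = 0.0114 with an estimated correlation). Cyp51, a sterol demethylase, fell from 16.8 ± 0.9 to 5.28 ± 0.01 FPKM. Of the LXR targets and cholesterol efflux genes 11 of 16 fell and 2 rose (camera, adjusted p = 0.00101; adjusted p = 0.0429 with an estimated correlation). Apoe, the apolipoprotein of lipid-loaded macrophages (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), fell from 169.8 ± 54.6 to 2.42 ± 0.45, a log2 change of -5.61 (SE 0.20, limma adjusted p = 6.36e-08). Glycolysis genes fell in 16 of 20 cases against 1 that rose (camera, adjusted p = 1.37e-07; adjusted p = 0.0561 with an estimated correlation), among them Pgam1, from 268.6 ± 10.5 to 122.4 ± 3.9, and the lactate exporter Slc16a3, from 25.7 ± 1.0 to 9.90 ± 0.59. The exception was Hk3, a hexokinase, from 64.1 ± 1.4 to 81.7 ± 4.7. NRF2 and oxidative stress genes fell in 12 of 16 cases against 1 that rose (camera, adjusted p = 3.64e-05; adjusted p = 0.0344 with an estimated correlation). Catalase (Cat) fell from 127.8 ± 3.9 to 51.6 ± 1.8 and Nqo1 from 5.30 ± 0.57 to 0.05 ± 0.05, while Sod2 rose from 16.8 ± 0.2 to 26.8 ± 1.6.

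Surface molecules for migration and adhesion were mostly lower in FLM_M, with 11 of 21 chemokine receptor and adhesion genes falling and 4 rising (camera, adjusted p = 0.00386; adjusted p = 0.189 with an estimated correlation). Emb, which codes for embigin (ENSMUSG00000021728, chromosome 13, 117208536 to 117274415), fell from 38.3 ± 2.8 to 0.03 ± 0.02 FPKM. Cx3cr1, the fractalkine receptor, fell from 61.6 ± 1.8 to 7.67 ± 0.52, whereas the integrin Itgal rose from 17.6 ± 0.9 to 41.3 ± 6.2. Outside these lists, large decreases among genes with at least 20 FPKM in BMM included those of Tgm2 (41.8 ± 1.4 to 0.43 ± 0.04), the transporter Abcc3 (25.1 ± 0.4 to 0.02 ± 0.02), Ly86 (67.7 ± 1.9 to 3.66 ± 0.22) and the metal transporter Slc11a1 (57.9 ± 3.7 to 6.96 ± 0.47). MHC class II presentation genes did not pass as a list (camera, adjusted p = 0.0951, 4 of 11 higher and 6 lower), but H2-Aa fell from 7.24 ± 0.26 to 0.14 ± 0.06 and H2-Ab1 from 8.49 ± 0.62 to 0.24 ± 0.03. Of the senescence, p53 target and immortalization genes 10 of 17 fell and 4 rose (camera, adjusted p = 0.0476; adjusted p = 0.143 with an estimated correlation). The cell cycle inhibitor and p53 target Cdkn1a fell from 123.4 ± 1.2 to 33.8 ± 1.4, Cdkn2a, the locus of the p16 and Arf tumour suppressors, rose from 1.71 ± 0.19 to 27.6 ± 2.4, and Trp53 rose from 22.3 ± 1.1 to 31.0 ± 2.5. Myc was at 21.6 ± 1.7 in BMM and 22.2 ± 3.7 in FLM_M (limma adjusted p = 0.883).

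The genes of macrophage identity went both ways between FLM_M and BMM. The M-CSF receptor gene Csf1r was at 368.0 ± 7.6 FPKM in BMM and 432.6 ± 28.3 in FLM_M, a log2 change of 0.23 (SE 0.06, limma adjusted p = 0.0108) that missed the threshold without BMM replicate 3 (adjusted p = 0.0503). Itgam (CD11b) was at 79.6 ± 4.6 in BMM and 96.3 ± 13.1 in FLM_M (limma, adjusted p = 0.0782, and 0.0169 without FLM_M replicate 2), and Pparg at 10.3 ± 0.5 and 9.80 ± 0.17 (adjusted p = 0.415). The complement gene C1qa rose from 858.8 ± 10.8 to 2016 ± 116. Within the M-CSF macrophage programme 12 of 21 genes were higher and 7 lower (camera, adjusted p = 0.438), with a median log2 change of 0.23 and a mean of -0.27. Adgre1 (F4/80) fell from 201 ± 11 to 140 ± 22. Cell cycle genes went both ways, 7 of 30 higher and 11 lower (camera, adjusted p = 0.438), and the proliferation marker Mki67 was at 90.7 ± 1.1 and 90.2 ± 6.3.

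In all, 5329 of 11952 genes differed between FLM_M and BMM in limma at an adjusted p under 0.05, 2716 higher and 2613 lower in FLM_M, and 840 of them differed at least 2-fold (447 higher, 393 lower). The median absolute log2 change was 0.22. Without scaling the median gene lay 0.05 (log2) higher in FLM_M and the calls divided into 3323 higher and 2240 lower. Of the 30 tested lists 11 passed (4 higher, 7 lower), 5 with an estimated correlation, and 9 (7 higher, 2 lower) on the count table. Adjusted over the list alone, the numbers of members called were those given above except for pattern recognition receptors (19 higher and 5 lower), Fc, complement and scavenger receptors (12 higher and 10 lower), NRF2 genes (13 lower), LXR targets (3 higher, 12 lower), senescence genes (5 higher) and cell cycle genes (12 lower). The edgeR test on the count table, named as the main test before the data were examined, called 1298 genes and DESeq2 827, and 1045 genes passed a limma test against a 1.5-fold change. The BMM libraries carried male and both fetal liver cultures female expression of the sex genes (values below), so that sex moved with each of these groups of genes.

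FLM_G cells had the expression of alveolar macrophage markers and of the response to GM-CSF, and had lost much of the M-CSF macrophage programme. All 19 tested alveolar macrophage markers rose against BMM, with a median log2 change of 4.93 (camera, adjusted p = 1.31e-13; adjusted p = 0.0189 with an estimated correlation). Of the 22 listed members only 6 reached 5 FPKM in BMM and 8 in FLM_M, against 19 in FLM_G. Members low in BMM and FLM_M could enter the test only through FLM_G, so the direction of these was set by the filter. The same holds for such members of the other lists in the comparisons of FLM_G. Chil3, a chitinase-like protein of alveolar macrophages (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), rose from 0.50 ± 0.15 FPKM in BMM to 1725 ± 62 in FLM_G. Car4, a carbonic anhydrase (ENSMUSG00000000805, chromosome 11, 84957786 to 84966044), was listed at 0 in all BMM and FLM_M libraries and at 665.5 ± 27.5 in FLM_G. Ear2, a ribonuclease whose close copies may have shared its reads, rose from 0.09 ± 0.03 to 794.9 ± 47.2, and Plet1 from 0.02 ± 0.03 to 520.8 ± 50.4. Siglecf, a lectin of alveolar macrophages and eosinophils, rose from 0.17 ± 0.04 to 30.2 ± 0.5, Itgax (CD11c) from 2.47 ± 0.31 to 153.2 ± 3.5, Marco from 5.27 ± 0.26 to 1185 ± 61, and Pparg, the transcription factor of alveolar macrophage development, from 10.3 ± 0.5 to 67.9 ± 4.3. GM-CSF receptor and STAT5 response genes rose in 12 of 16 cases against 2 that fell (camera, adjusted p = 0.000281; adjusted p = 0.186 with an estimated correlation). The receptor genes Csf2ra and Csf2rb rose from 129.4 ± 13.6 to 407.7 ± 41.3 and from 23.1 ± 0.4 to 200.8 ± 12.5. The kinase gene Pim1 rose from 12.4 ± 0.9 to 111.4 ± 4.4, while the repressor gene Bcl6 fell from 10.4 ± 0.4 to 2.13 ± 0.10.

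**Figure D1:**
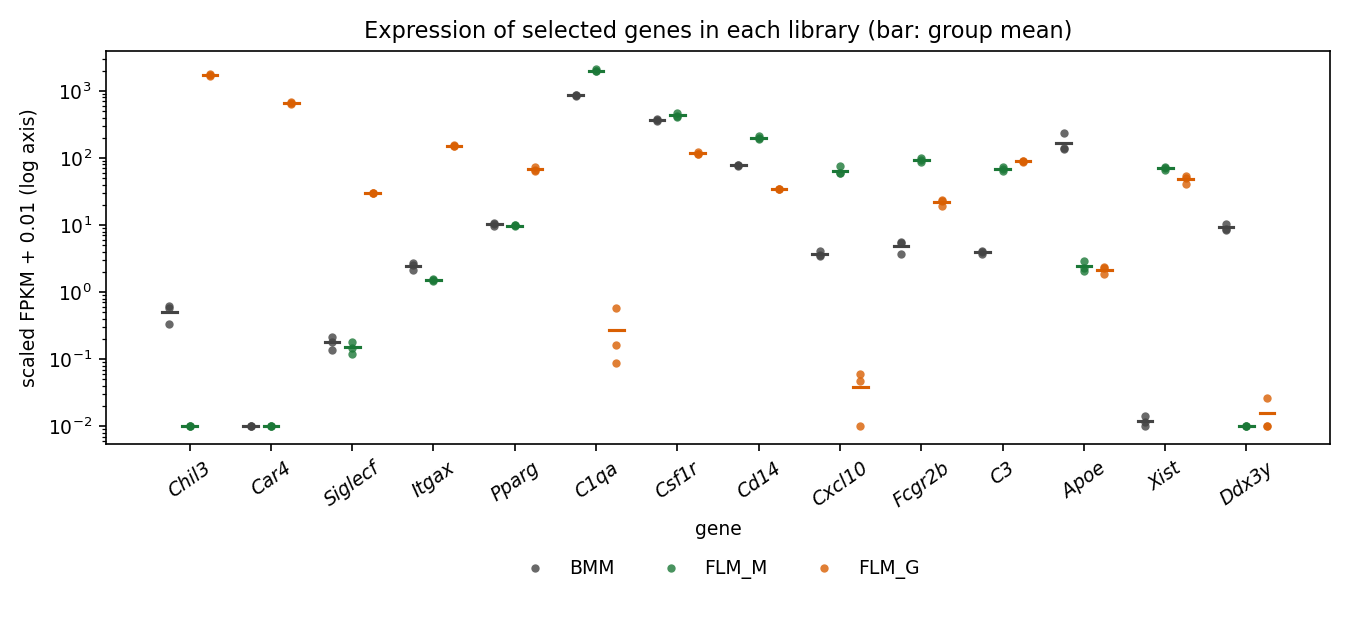
Scaled FPKM plus 0.01 on a log axis for 14 genes, with 1 point per library, a bar for each group mean, and colours for BMM, FLM_M and FLM_G (3 libraries each). Siglecf and Itgax stood highest in FLM_G (30.2 and 153.2 FPKM), C1qa lowest there (0.27 FPKM), and Ddx3y was expressed only in the BMM libraries (9.20 FPKM).

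Of the M-CSF receptor and M-CSF macrophage programme, 17 of 21 genes fell and 4 rose in FLM_G against BMM (camera, adjusted p = 3.09e-07; adjusted p = 0.0202 with an estimated correlation). C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803) fell from 858.8 ± 10.8 to 0.27 ± 0.27 FPKM, and C1qb and C1qc, which neighbour it, from 1377 ± 29 to 2.0 ± 0.1 and from 615.8 ± 7.4 to 0.58 ± 0.09. Folr2 fell from 125.8 ± 0.6 to 0.04 ± 0.07, Stab1 from 94.9 ± 2.2 to 0.02 ± 0.01, and Gas6, a ligand of the TAM receptors that bind dying cells, from 151.5 ± 1.8 to 0.03 ± 0.06. Csf1r fell from 368.0 ± 7.6 to 118.8 ± 4.7. The transcription factor gene Maf fell from 56.2 ± 2.4 to 0.24 ± 0.05, and Klf4 rose from 6.18 ± 0.46 to 60.8 ± 3.0. The members that rose included the mannose receptor gene Mrc1, from 44.7 ± 4.2 to 232.4 ± 18.5, and Mertk, from 9.11 ± 0.40 to 64.0 ± 1.6. Pan-macrophage genes went both ways, 11 of 23 higher and 10 lower (camera, adjusted p = 0.925), and the sign of their median depended on the scaling. Among their surface molecules, Csf1r fell and Mertk rose, as given above. Others that were lower included Adgre1 at 72.0 ± 4.1, Itgam at 26.5 ± 2.7, Cd14 at 34.4 ± 0.3 and Fcgr1 at 19.3 ± 0.3 in FLM_G against 201 ± 11, 79.6 ± 4.6, 78.2 ± 1.2 and 59.7 ± 1.0 in BMM (limma adjusted p of 3.18e-06 or less for each of these 4).

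Interferon-stimulated genes fell in FLM_G against BMM, 29 of 30 members against 1 that rose, the opposite of FLM_M (camera, adjusted p = 1.92e-09; adjusted p = 0.135 with an estimated correlation). Ifit3 fell from 14.4 ± 0.9 to 0.70 ± 0.08 FPKM and Oas3 from 19.6 ± 0.6 to 1.10 ± 0.24. Gbp2 was the member that rose, by 0.28 (SE 0.07), and was lower in FLM_G without scaling. Outside that list Ifitm3, an inhibitor of virus entry, fell from 300.1 ± 7.6 to 0.25 ± 0.24. Of the cell cycle genes 29 of 30 fell and none rose (camera, adjusted p = 2.15e-11; adjusted p = 0.0114 with an estimated correlation), with a median log2 change of -1.18. Kif11 fell from 32.5 ± 1.1 to 8.55 ± 0.28 and Plk1 from 61.2 ± 2.5 to 16.9 ± 0.5. MHC class II presentation genes rose in 9 of 11 cases and fell in 2 (camera, adjusted p = 0.00234; adjusted p = 0.135 with an estimated correlation), Cd74 from 35.9 ± 0.8 to 419.8 ± 39.7 and H2-Aa from 7.24 ± 0.26 to 38.4 ± 3.0. Glycolysis genes fell in 15 of 20 cases and rose in 3 (camera, adjusted p = 0.00339; adjusted p = 0.216 with an estimated correlation). Tpi1 fell from 186.6 ± 14.9 to 53.1 ± 5.4, while Aldoc rose from 8.09 ± 0.36 to 64.6 ± 3.1.

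Genes of lipid synthesis, uptake and storage were higher in FLM_G than in BMM, whereas LXR targets and cholesterol efflux genes went both ways (camera, adjusted p = 0.896, 7 of 16 higher and 8 lower). Cholesterol synthesis genes rose in 22 of 24 cases and fell in none (camera, adjusted p = 3.92e-08; adjusted p = 0.0114 with an estimated correlation), Mvd from 10.7 ± 0.6 to 96.4 ± 6.4 FPKM and Fdft1 from 12.8 ± 0.3 to 45.5 ± 2.5. The count table had Fdft1 lower in FLM_G, but its counts may be reads of the opposite strand (closing section). Genes of fatty acid uptake, storage and oxidation rose in 16 of 21 cases and fell in 1 (camera, adjusted p = 1.93e-05; adjusted p = 0.021 with an estimated correlation), the lipid carrier Fabp5 from 29.0 ± 0.8 to 614.3 ± 17.2 and Fabp4 from 1.10 ± 0.08 to 71.8 ± 5.2. Cd36 was the exception, from 194.6 ± 9.5 to 136.6 ± 32.1. Lysosome and vacuolar ATPase genes rose in 24 of 34 cases and fell in 5 (camera, adjusted p = 0.00029; adjusted p = 0.0429 with an estimated correlation). Ctsk, the cathepsin of osteoclasts, rose from 1.62 ± 0.26 to 1078 ± 5, Atp6v0d2 from 5.32 ± 0.29 to 954.2 ± 49.9, and Ctsl fell from 875.6 ± 29.5 to 316.1 ± 6.8. The 15 mitochondrially encoded genes all rose (camera, adjusted p = 7.59e-06; adjusted p = 0.343 with an estimated correlation), and their share of all FPKM was 20.6% to 20.8% in the FLM_G libraries and 9.37% to 11.9% in the others. Immediate early and heat shock genes rose in 10 of 17 cases and fell in 3 (camera, adjusted p = 0.0187; adjusted p = 0.343 with an estimated correlation), Egr2 from 0.77 ± 0.06 to 69.9 ± 12.7 and Ier2 from 14.7 ± 0.1 to 96.8 ± 13.2. Egr2, low in BMM and FLM_M, could enter the test only through FLM_G.

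Other single genes also stood out in FLM_G. The chemokine gene Ccl6 (ENSMUSG00000018927, chromosome 11, 83587882 to 83593087) rose from 17.7 ± 1.6 to 10070 ± 46 FPKM, and took 1.49% to 1.58% of all FPKM in the FLM_G libraries. Mcemp1 rose from 0.58 ± 0.03 to 301.2 ± 24.2, Il1a from 0.08 ± 0.10 to 97.8 ± 2.0, and the fungal lectin receptor Clec4n from 3.00 ± 0.35 to 522.7 ± 30.3. Nov, a matrix-associated signalling protein, was listed at 0 in all BMM and FLM_M libraries and at 214.4 ± 12.7 in FLM_G. Ccl7 fell from 151.2 ± 10.8 to 0.82 ± 0.20, the protease gene Adam8 from 388.1 ± 5.7 to 3.15 ± 0.65, Pf4 from 192.2 ± 4.4 to 0.58 ± 0.12, and Apoe from 169.8 ± 54.6 to 2.14 ± 0.27. Tlr2 rose from 23.3 ± 0.8 to 89.8 ± 2.1, whereas Tlr9, the sensor of unmethylated DNA, fell from 1.66 ± 0.17 to 0.08 ± 0.03. Tlr4 had 21.1, 15.9 and 13.9 FPKM in the FLM_G libraries against 2.25, 2.95 and 9.41 in BMM (limma adjusted p = 0.0188), a call lost when BMM replicate 1 (adjusted p = 0.068), BMM replicate 2 (0.0611) or FLM_G replicate 1 (0.0555) was left out. Cdkn2a rose from 1.71 ± 0.19 to 17.1 ± 3.0 and the p53 target Phlda3 from 4.44 ± 0.05 to 96.2 ± 8.4, although senescence genes as a list did not pass (camera, adjusted p = 0.438, 7 of 17 higher and 4 lower) and their median changed sign with the scaling. Trp53 fell from 22.3 ± 1.1 to 15.7 ± 1.1, and Myc rose from 21.6 ± 1.7 to 37.9 ± 3.4. The count table did not show the fall of Trp53, but its counts may be reads of the opposite strand (closing section).

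Between FLM_G and BMM 8125 of 11952 genes differed in limma, 4044 higher and 4081 lower in FLM_G, of which 2241 differed at least 2-fold (1176 higher, 1065 lower), and the median absolute log2 change was 0.39. Of the 30 lists 13 passed, 6 of them with an estimated correlation, and adjusted over the list alone the numbers of members called did not differ. Without scaling, the FPKM of FLM_G lay a median 0.34 (log2) below BMM, and the calls divided into 2081 higher and 6775 lower. With quantile normalization the median log2 change of the mitochondrially encoded genes fell from 1.78 to 0.20 and that of lysosome genes from 0.73 to 0.28. The changes above are relative to the shift, and no list that passed changed the sign of its median under any of the 4 other scalings, but without scaling 12 of 34 lysosome genes, 6 of 17 immediate early genes and 4 of 21 fatty acid genes were called lower. The edgeR test on the counts called 2457 genes, DESeq2 2201, and the test against a 1.5-fold change 2740.

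FLM_G and FLM_M, both from fetal liver and grown in different media, were the most distant pair by median absolute log2 change and by genes changed at least 2-fold. By all genes called the order turned over in the fits of only the 6 libraries compared (8054, against 8089 for FLM_G against BMM). Of the interferon-stimulated genes 29 of 30 were lower and 1 higher in FLM_G (camera, adjusted p = 1.22e-12; adjusted p = 0.0808 with an estimated correlation), with a median log2 change of -3.93. Isg15 was at 182.8 ± 22.9 FPKM in FLM_M and 3.47 ± 0.29 in FLM_G, and Usp18 at 106.5 ± 6.1 and 0.68 ± 0.23. MHC class I presentation genes were lower in 15 of 17 cases and higher in none (camera, adjusted p = 1.56e-05; adjusted p = 0.0429 with an estimated correlation), with the class I light chain B2m at 3445 ± 134 and 3288 ± 184 (limma adjusted p = 0.411). MHC class II genes were higher in 8 of 11 cases and lower in 3 (camera, adjusted p = 0.0133; adjusted p = 0.188 with an estimated correlation), Cd74 at 15.5 ± 1.3 in FLM_M and 419.8 ± 39.7 in FLM_G. All 19 tested alveolar macrophage markers were higher (camera, adjusted p = 3.81e-12, and adjusted p = 0.0202 with an estimated correlation), with a median log2 change of 4.17 and Chil3 listed at 0 in the 3 FLM_M libraries. As against BMM, markers low in the other cultures could enter this test only through FLM_G. Of the M-CSF programme 16 of 21 genes were lower and 3 higher (camera, adjusted p = 7.59e-06; adjusted p = 0.0241 with an estimated correlation).

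All 24 cholesterol synthesis genes were higher in FLM_G than in FLM_M (camera, adjusted p = 5.77e-10; adjusted p = 0.0114 with an estimated correlation), with a median log2 change of 1.92. Mvd was at 4.72 ± 0.13 FPKM in FLM_M and 96.4 ± 6.4 in FLM_G, and Cyp51 at 5.28 ± 0.01 and 58.3 ± 3.1. Fatty acid genes were higher in 18 of 21 cases and lower in none (camera, adjusted p = 1.59e-05; adjusted p = 0.021 with an estimated correlation), with Lpl, the lipoprotein lipase, at 155 ± 11 and 1233 ± 112. Without scaling 12 fatty acid genes were higher and 3 lower, and their median log2 change fell from 0.86 to 0.39. All 30 cell cycle genes were lower in FLM_G (camera, adjusted p = 1.08e-10; adjusted p = 0.0114 with an estimated correlation), Mcm2 at 60.1 ± 2.7 and 21.1 ± 0.8. GM-CSF and STAT5 response genes were higher in 14 of 16 cases and lower in 1 (camera, adjusted p = 2.95e-05; adjusted p = 0.143 with an estimated correlation), with the chemokine gene Ccl17 listed at 0 in FLM_M and BMM and at 71.9 ± 2.1 in FLM_G. Ccl17 could thus enter the test only through FLM_G, so its direction was set by the filter. The 15 mitochondrially encoded genes were all higher (camera, adjusted p = 1.24e-05; adjusted p = 0.347 with an estimated correlation). Lysosome genes were higher in 23 of 34 cases and lower in 7 (camera, adjusted p = 0.00158; adjusted p = 0.0619 with an estimated correlation), which without scaling became 17 higher and 16 lower. Alternative activation genes were higher in 8 of 10 cases and lower in 2 (camera, adjusted p = 0.0038; adjusted p = 0.0648 with an estimated correlation), including Egr2 at 0.76 ± 0.06 and 69.9 ± 12.7 and Tgm2 at 0.43 ± 0.04 and 12.7 ± 1.1. Tgm2 stood at 41.8 ± 1.4 in BMM, above FLM_G, so its difference was a low level in FLM_M. Egr2, low in both BMM and FLM_M, could enter the test only through FLM_G, so its direction was set by the filter. Among the largest single differences, Mfge8, a bridge to dying cells, was at 4.59 ± 0.28 in FLM_M and 1563 ± 103 in FLM_G, and Pcp4l1 was at 144.5 ± 8.2 in FLM_M and listed at 0 in FLM_G.

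**Figure D2:**
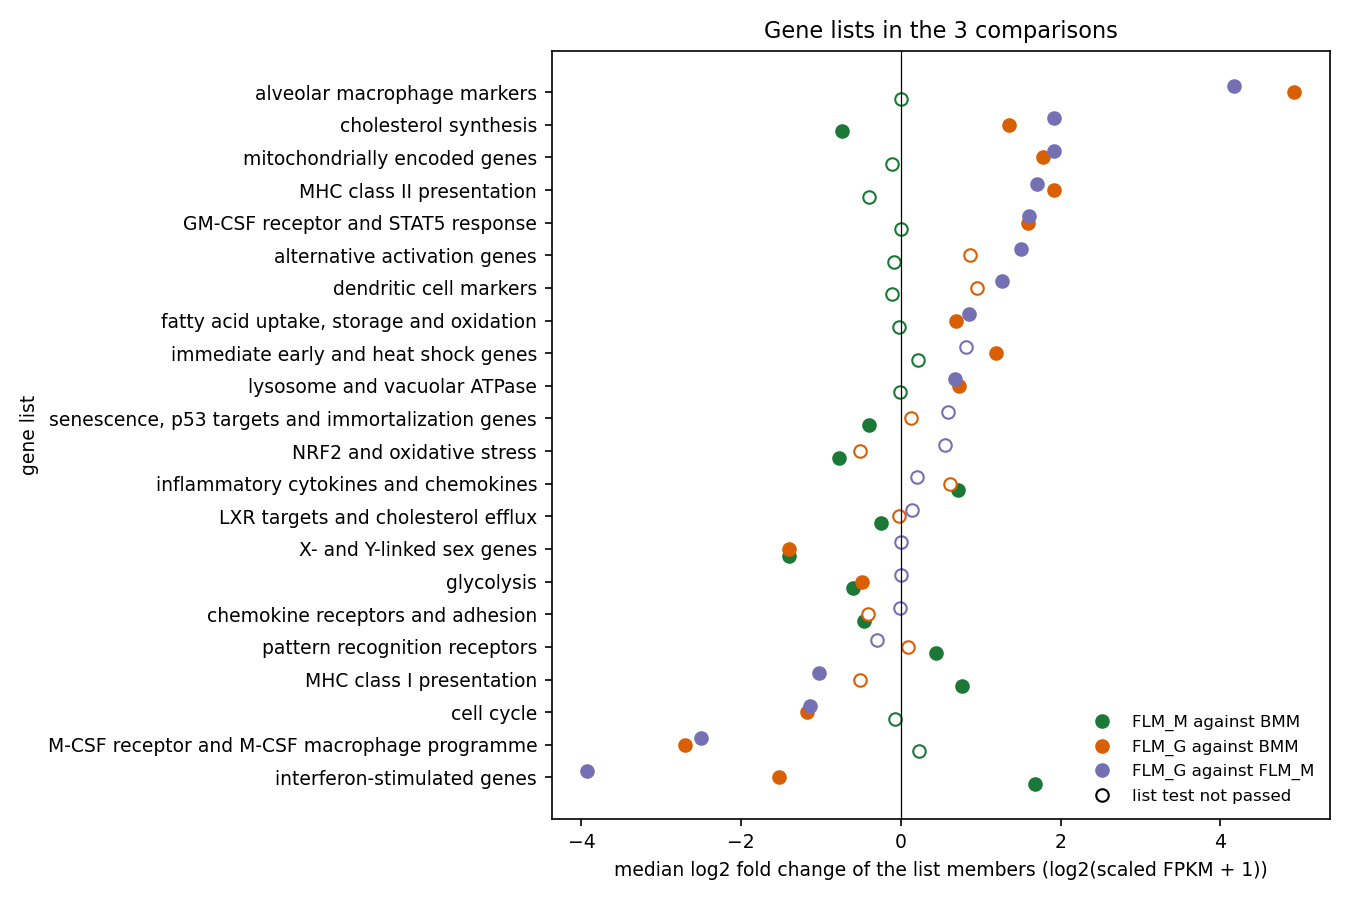
Median log2 fold change over the tested members of each gene list that passed in at least 1 comparison, with 1 row per list and a colour per comparison; filled points passed camera at an adjusted p under 0.05 with the preset correlation, open points did not. Interferon-stimulated genes lay at 1.68 in FLM_M against BMM and at -1.53 in FLM_G against BMM, and alveolar macrophage markers at 4.93 in FLM_G against BMM.

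Between FLM_G and FLM_M 8441 of 11952 genes differed in limma, 4246 higher and 4195 lower in FLM_G, 2563 of them at least 2-fold (1345 higher, 1218 lower), with a median absolute log2 change of 0.44. Of the lists 13 passed, and 6 with an estimated correlation; adjusted over the list alone, 24 lysosome genes were higher and the other numbers did not differ. Without scaling the median gene lay 0.39 (log2) lower in FLM_G and the calls divided into 2218 higher and 7075 lower. With quantile normalization the median log2 change of the mitochondrially encoded genes fell from 1.91 to 0.22 and that of lysosome genes from 0.68 to 0.08. The edgeR test on the counts called 2850 genes, DESeq2 2631, and the test against a 1.5-fold change 3162.

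Some changes against BMM were shared by both fetal liver cultures. Of the calls against BMM, 1015 genes were higher in both FLM_M and FLM_G and 1165 lower in both, where lists independent of each other would share 919 and 892.2. Another 1010 genes were higher in FLM_M and lower in FLM_G, and 892 the reverse, against 927.4 and 884.1 for independent lists. The covariance of the fold changes was 0.0644, above the 0.00942 of 100 simulations without effect. Their correlation was 0.0991 against a simulated 0.494, but the simulated value is set by the shared controls alone and does not bear on shared effects. The simulations shared a mean of 0.03 and at most 1 call of the same direction, against 2180 here. A setting without effects cannot show how much the shared controls add where effects are present. With 3 BMM libraries the controls could not be divided, so part of the excess over independent lists may come from the shared controls. Igf2bp3, an RNA-binding protein of fetal cells, rose in both, from 0.46 ± 0.09 FPKM in BMM to 15.7 ± 1.3 in FLM_M and 12.6 ± 0.6 in FLM_G, and the chromatin protein gene Hmga1 fell in both, from 150.9 ± 2.1 to 31.0 ± 1.1 and 33.8 ± 4.5. The fetal-stage genes as a list, of which 5 were tested, did not pass against BMM (camera, adjusted p = 0.202 for FLM_M and 0.969 for FLM_G), and the sign of their median in FLM_G depended on the scaling.

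Most markers of other cell types were at or near background in the 3 cultures. None of the 15 fibroblast markers reached 5 FPKM in any group, and the median over the hepatocyte, lymphocyte, erythroid and megakaryocyte, and mast cell, basophil and eosinophil markers was 0 in each group. Of the hepatocyte markers only Trf (127.3 FPKM in FLM_G, 31.7 in FLM_M, 5.01 in BMM) and Rbp4 (62.4 in FLM_G, listed at 0 in the others) reached 5 FPKM. Among neutrophil markers S100a8 and Mmp8 reached it (53.3 and 18.7 FPKM in FLM_G), 1 of them also in FLM_M and neither in BMM. Among mast cell markers Slc6a4 reached it, and among erythroid and megakaryocyte markers Epor and Pf4. Il7r was the only lymphocyte marker above 5 FPKM (23.2 in BMM, 18.9 in FLM_M, 12.1 in FLM_G), and Kdr the only endothelial one (6.63 in FLM_M). Dendritic cell markers passed in FLM_G against FLM_M, 5 of 6 tested members higher and 1 lower (camera, adjusted p = 0.0371; adjusted p = 0.143 with an estimated correlation), led by Cd24a at 0.41 ± 0.13 and 15.4 ± 0.2 FPKM. In BMM Cd24a stood at 18.3 ± 0.1 FPKM, above FLM_G, so its difference was a low level in FLM_M. Only 6 of the 15 listed dendritic cell markers could be tested. Osteoclast markers did not pass in FLM_G against BMM (camera, adjusted p = 0.064, 5 of 9 higher and 1 lower). The X- and Y-linked sex genes separated BMM from both fetal liver cultures. Xist, the RNA of the inactive X chromosome, was at 70.9 ± 3.6 in FLM_M and 48.5 ± 6.8 in FLM_G and under 0.01 in every BMM library, whereas the Y-linked Ddx3y was at 9.20 ± 1.09 in BMM, listed at 0 in all FLM_M libraries and at 0.02 or less in FLM_G. As a list they passed in FLM_M against BMM (camera, adjusted p = 0.00495; adjusted p = 0.077 with an estimated correlation) and in FLM_G against BMM (adjusted p = 0.0371; adjusted p = 0.143 with an estimated correlation), 4 of 5 lower and 1 higher in each. Sex, culture origin and medium could therefore not be separated in the comparisons with BMM.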

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

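The tests in this part were chosen only after the result was seen. The deposited count table, which the comparisons of the report do not use, held a signal in genes that the FPKM give as silent: 36.1% of all counts lay in genes with a mean FPKM under 0.5, which held 0.181% of the FPKM. This signal in data outside the main measurement is what drew attention.

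If the counts were a shallow sample of the reads behind the FPKM, silent genes would hold under 1% of them, so the 36.1% argues against that explanation. If reads had been counted on the strand opposite to the gene, a silent gene overlapping an expressed gene on the other strand would take its reads, and over 3877 such genes the counts followed the reads of the partner with a Spearman rho of 0.83 (0.424 with the gene's own FPKM). In 466 of them whose partner was worth at least 100 reads, the median count was 83.7% of the partner's reads. The mitochondrial gene mt-Nd6, opposite to most mitochondrial genes, took 6.88% of the counts and 0.028% of the FPKM. A count setting for the wrong strand may therefore explain the table, and no biological explanation was tested.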

How the results depend on the processing

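Quantile normalization and the pseudocount of 0.1 on scaled values were chosen after seeing the data. The bound set for no change was 1.5-fold of the main value. With RLE or upper-quartile scaling, the stricter filter, only the 6 libraries compared, or quantile normalization, the numbers of genes changed, of genes changed at least 2-fold and the median absolute changes stayed within it. The stricter filter, which tests fewer genes, called 3837 (FLM_M against BMM), 5719 (FLM_G against BMM) and 5896 (FLM_G against FLM_M) genes. Of these 572, 1639 and 1859 changed at least 2-fold. The replicate numbers gave no clear pairing over all groups: deviations from the group means correlated at -0.0771 to 0.0899 in 9 same-numbered pairs and -0.0958 to 0.0724 in the others. Between BMM and FLM_G alone, same-numbered pairs lay at 0.0534 to 0.0899 and the others at -0.051 to -0.0232, so a weak pairing there remains open. With the replicate number as a block, 5140 (FLM_M against BMM), 8018 (FLM_G against BMM) and 8386 (FLM_G against FLM_M) genes were called.

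In the same order of comparisons, edgeR on the counts called 1298, 2457 and 2850 genes, DESeq2 827, 2201 and 2631, and the test against a 1.5-fold change 1045, 2740 and 3162, the last by its own construction. On simulated counts of the table's depth and spread (FLM_G against BMM, 6951 genes), edgeR recovered 5.97% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 100% of those changed 4-fold. The changes were planted only in genes with higher counts. Changes of 1.5-fold were thus mostly missed, but depth was not varied, so its part was not separated from that of the spread. The part of the strand was not tested. The pseudocount of 0.1 gave 1277 genes of at least 2-fold in FLM_M against BMM, since a smaller pseudocount widens folds of low genes, and together with no scaling 1303, 3481 and 3948, where both choices contributed. The median absolute change was 0.4251 in edgeR for FLM_M against BMM, and 0.5186, 0.64 and 0.737 in DESeq2; the cause was not tested. It was 0.1013, 0.1707 and 0.1884 with no filter, and 0.1104, 0.1983 and 0.2301 with neither scaling nor filter, since low genes entered. Without scaling and with the pseudocount of 0.1 it was 0.6193 in FLM_G against BMM and 0.6883 in FLM_G against FLM_M. With an estimated correlation in camera 5, 6 and 6 lists passed, by a wider error; with the block 10, 12 and 13 passed, without scaling 12, 17 and 17, and on log2 CPM of the counts 9 (7 higher and 2 lower, against 4 and 7), 12 and 13. The overlap of 2180 calls was 456 in edgeR, 298 in DESeq2 and 273 for calls of at least 2-fold.

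Leaving out each library in turn gave 4192 to 5509, 7239 to 8063 and 7606 to 8242 genes, 744 to 854, 1949 to 2225 and 2266 to 2555 of at least 2-fold, medians of 0.2119 to 0.2247, 0.3814 to 0.3981 and 0.427 to 0.4478, 10 to 12, 11 to 14 and 11 to 14 lists, and an overlap of 1626 to 2258. Of 3936 values of named genes in these fits, 3879 kept their direction and side of the threshold, 31 lost and 26 gained a call, and none reversed.

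Some named genes reversed (log2 fold changes). In FLM_G against BMM these were B2m with quantile normalization (-0.6723), Gbp2 without scaling (-0.08111; -0.09579 with pseudocount 0.1; -0.08111 with no filter) and H2-T23 under the same settings (-0.01867, -0.01903 and -0.01867). On the counts in that comparison they were Cd24a (0.774, DESeq2), Fdft1 (-1.199 in edgeR, -1.234 in DESeq2), Il4ra (0.0005674, edgeR), Pltp (1.205 and 1.165) and Trp53 (0.1517 and 0.08721). In FLM_G against FLM_M it was Cdkn2a (0.05893, DESeq2). In FLM_M against BMM they were Calr (0.04736, edgeR), H2-Eb1 (0.6397, DESeq2), Il4ra (0.2375 in edgeR, 0.1664 in DESeq2) and Itgax (0.03997, edgeR). The counts may be reads of the opposite strand, so reversals on them need not concern the named gene. The cause was not tested gene by gene.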

Other observations

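Apart from the test on neighbouring genes, the tests in this part were chosen only after the result was seen, as were the bounds that define its patterns and the genes it names.

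In FLM_M 23 genes on 14 chromosomes had a mean under 0.5 FPKM while both BMM and FLM_G had at least 5, among them Aldoc, Axl, H2-Aa, Phgdh and Tgm2; the same held for 67 genes in FLM_G and 3 in BMM against the other 2 groups. A failed FPKM estimate was argued against by the deposited counts of these genes, which in FLM_M stood at 2.08% of their level in BMM (7 against 278 counts over 17 of the genes). Loss of chromosome segments holding several genes was argued against by the 44 nearest expressed neighbours, with a median log2 change of -0.072 and none under -3. Loss or silencing of single genes, or the medium, may explain the pattern, and neither was tested; fetal liver origin and female expression were shared by FLM_G, which expressed these genes.

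Over 6563 protein-coding genes, the medians of some chromosomes shifted between cultures, with 13 of 60 medians past an adjusted p of 0.05 against random gene sets. Those of FLM_G against FLM_M use the libraries of the other 2 comparisons and are not independent of them. In the comparisons with BMM 5 were of at least 0.2. In FLM_M these were chromosomes 12 (median log2 change -0.359), 19 (-0.272) and 6 (0.215). In FLM_G they were chromosome 1 (-0.247) and the X chromosome (0.355), strongest in runs of genes from 151571186 to 191833050 and from 100494291 to 170019281. Windows of 41 neighbouring genes passed a threshold from shuffled genes in 169 of 181 cases on chromosome 12 and 102 of 232 on chromosome 19. On chromosome 1 only 70 of 269 passed and on X 44 of 155, so these shifts were concentrated in parts of the chromosome. For these 5, GC content and gene length were argued against by the 79% or more of each shift that correction kept, and sex as the whole cause of the X shift by a difference of 0.394 between the 2 fetal liver cultures. Copy number may explain these 5, and their genes of low and of high expression moved the same way by at least 0.148. That is little evidence for it, since the 5 were chosen for chromosome medians of at least 0.2. On X in FLM_G the median was 0.148 in genes of low and 0.461 in genes of high expression. The bound of this test was set after the values were seen, and DNA was not measured. Of the other 8, GC content and gene length were argued against for 6 (at least 85.8% kept) and left open for chromosomes 6 and 14 in FLM_G against FLM_M (64.9% or more kept), and copy number could not be decided for the 8 together, since on chromosomes 14 and 15 in FLM_G against FLM_M the highly expressed genes moved by 0.00113 and 0.001994 against their chromosome (lowest upper bootstrap limit 0.149).

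Each division of the 6 libraries of a comparison into 3 and 3 was tried, which makes 10 splits, and the real split gave the largest result (1 of 10) for each number. In FLM_M against BMM the real split called 5457 genes (highest other 4), 841 of at least 2-fold (4) and 10 lists (7). In FLM_G against BMM it called 8089 genes (1), 2237 of at least 2-fold (1) and 12 lists (10). In FLM_G against FLM_M it called 8054 genes (3), 2564 of at least 2-fold (3) and 13 lists (10). With 10 splits a share under 0.05 cannot be reached. Every other split mixed libraries of both groups on each side, which widens the spread, so its few gene calls followed from the design. Such splits still held part of the real difference, so the lists that passed in them do not measure chance.

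C5ar1 stood at 27.2, 23.8 and 226.7 FPKM in the 3 FLM_M libraries, with 133, 141 and 130 deposited counts. In BMM it stood at 233, 232 and 230 FPKM, with 48, 77 and 83 counts. Without FLM_M replicate 3 its log2 change in FLM_M against BMM was -3.127 (limma adjusted p = 0.00762), a call not made with all libraries. That fit kept the 2 FLM_M libraries whose FPKM lay far below that of replicate 3, although their counts were level with it. The counts were not lower in FLM_M than in BMM, so a lower level of C5ar1 in FLM_M is not shown. C5ar1 was 1 of 20 genes in which 1 library of a group lay over 4-fold from both others.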
